A study of Mus musculus with 24 samples.

How the data were processed

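The deposited values were analysed as the authors gave them, and no reads were processed. Per the submitters' processing notes, the reads were checked with FastQC, aligned with HISAT2 to the mouse build mm9, assembled with StringTie and compared with limma, with no versions given. The authors deposited 3 tables of expression values per gene, 1 for the pancreatic libraries, 1 for the intestinal libraries and 1 for the macrophage libraries. In each table the deposited values were log2 values with 1 added before the log, and the unit before the log was not stated. They had been quantile normalized within each table: sorted from highest to lowest, the values above 0 were the same in every library of a table, with a largest difference of 0.00035 in the pancreatic, 0 in the intestinal and 0.00016 in the macrophage table. The number of reads behind a value could not be recovered, so the depth of the libraries is unknown and no counting interval or floor is given. Since the tables were normalized separately, no library of 1 table was set against a library of another, and the tissue difference compared changes taken within each table. Gene positions are not printed, because the annotation at hand was for a later build than mm9.

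The tables with tuft libraries also held the authors' own statistics. Their deposited fold change was 2 to the power of the difference between the group means, and their deposited p-value and false discovery rate were those of limma's moderated test without a trend, which returned the same p to within 1e-14 (pancreas) and 1.3e-14 (intestine) on the log10 scale. All values and tests in the text come from the fits described here, except where the authors' calls are named.

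A value of 0 in these tables was read as listed at 0, not as absence of the transcript, because Gapdh was listed at 0 in 2 intestinal libraries and Tbp in 1 pancreatic library. Where a group held a 0, the values of its 3 libraries are given in place of a mean and SD. Where all 3 libraries of a group were at 0, no difference from that group is given for the gene. An interaction or tissue difference that contains such a group is given, as at Siglecf and Ptprc, and depends in part on the value added before the log. Some symbols had been converted to dates in the deposited tables (16 genes in the pancreatic, 14 in the intestinal and 15 in the macrophage table); these genes stayed in the tests and are not named.

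The choices below were made before the data were examined, except where stated. Each gene of a table was tested with limma (version 3.58.1 in R 4.3.3), with the moderated test of eBayes and a trend of the variance with the mean level, on the deposited log2 values without further scaling and with no gene removed. The test was two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. All 4 macrophage groups entered 1 fit. The interaction of LPS and PGD2 was the change with PGD2 after LPS minus the change with PGD2 without LPS. The difference between the tissues was the tuft change in the pancreas minus that in the intestine, fitted over the genes that both tables held. The p-values measure the spread between these samples only. With 3 libraries against 3, an exact test of a single gene cannot go below 0.1, so the adjusted p rest on limma's pooling of the variance over genes. Differences are on the log2 scale with their standard error (SE), and group means are log2 values with their SD over 3 libraries.

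Whether the libraries paired was checked by correlating, across genes, the residuals of libraries that carry the same number in different groups; genes are not independent replicates. Same-number pairs had r of 0.021 to 0.038 in the pancreas and other pairs −0.033 to 0.003, so that 6 of 6 libraries were closest to their own number. In the macrophages the 18 same-number pairs had r of 0.233 to 0.591 and the others −0.415 to −0.083, with 12 of 12 closest to their own number. A fit with the number as a block was therefore run as an alternative. The descriptions of the pancreatic libraries also share 1 number per tuft and non-tuft pair, read as a mouse. The main fit takes the 6 libraries as independent. In the pancreas it called 244 genes, and the fit with the block called 193 (122 higher and 71 lower).

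Lists of genes, 43 in all, were written from general knowledge of the cell types and pathways; 27 were for the tuft tables and 28 for the macrophage table. A list was tested where at least 3 members were in the table, with limma's camera at its preset correlation between genes of 0.01, which compares the members with all other genes, and the p-values were adjusted over the lists of a comparison. The same test with a correlation estimated from the residuals was run beside it. A call lost there does not by itself show that correlated genes made it, as given in the part on processing. The alternative fry tests whether the members of a list move, on balance, one way, and does not compare them with other genes. Where a list has a paragraph or a sentence of its own, the number of its members past the threshold is given over all genes tested and adjusted over the list alone.

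Genes were named by a rule. It took the 10 largest rises and the 10 largest falls in each comparison among genes past the threshold, without overlap between the libraries of the groups and with a mean value of at least 10 (before the log) in the higher group, leaving out clone-type, ribosomal pseudogene and unnamed features. It added up to 4 members of each list with the smallest adjusted p, and genes fixed in advance for every comparison. For the interaction and the tissue difference only the largest changes and the fixed genes were named. The text names fewer than the rule allows, and a gene outside it is said to have been chosen after its values were seen.

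The alternatives were limma without the trend, 0.1 in place of 1 added before the log, a mean value of at least 5 before the log, scaling by the median of ratios, repeated quantile normalization, the number as a block, a fit of only the 2 groups compared, and leaving out each library. Fits of only the genes with no value at 0, and of genes with a mean log2 value of at least 1, were added after the data were seen. In simulated tables of the same size and spread, limma recovered 74% of genes changed by a log2 of 5 and 14% of those changed by 2 with the spread of the pancreas. The shares were 80% and 32% with that of the intestine, and 100% and 100% with that of the macrophages without LPS. The share of false calls was 3.9% in the pancreas, 5.6% in the intestine, 0% in the tissue difference, 3.9% with PGD2 alone, 5.5% with PGD2 after LPS, 7.7% with LPS and 4.7% in the interaction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.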

Results

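Messenger RNA was sequenced from 24 mouse libraries in 8 groups of 3. From KC mice, which carry KrasG12D switched on by Ptf1a-Cre and bear PanIN (pancreatic intraepithelial neoplasia) at 8–9 months, sorted pancreatic tuft cells and non-tuft cells were taken. From wild-type littermates the same populations were taken from the proximal 5 cm of the small intestine. Cells were stained for Cd45, EpCAM and Siglec F, and dead and dying cells were excluded with DAPI and Annexin V. The description of the sort is cut off in the records, so the gates that define tuft and non-tuft cells were not read. The other 4 groups were bone-marrow-derived macrophages of male CD1 mice given vehicle (methyl acetate) or 10 µM prostaglandin D2 (PGD2), without LPS or after 4 h with 100 ng/ml LPS (bacterial lipopolysaccharide), and collected 24 h later. The depth of the libraries is unknown. Within groups, the correlation of libraries across genes was 0.724 to 0.845 in the pancreas, 0.817 to 0.879 in the intestine and 0.967 to 0.98 in the macrophages. Genes listed at 0 in at least 1 library made up 39.1% of the pancreatic, 37% of the intestinal and 4.9% of the macrophage table. A library had 1236–2460 such genes in the pancreas, 1390–2122 in the intestine and 108–152 in the macrophages.

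The first comparison asked which transcripts set tuft cells apart from the other sorted cells of the PanIN-bearing pancreas. The tuft libraries held higher levels of tuft-cell core genes (18 of 22 measured), of genes of prostaglandin and leukotriene metabolism (7 of 12), and of some genes of the brush border and cytoskeleton (4 of 12). The non-tuft libraries held higher levels of acinar genes (15 of 20) and of 5 of 17 endocrine genes, among them Ppy and Sst. Of 12274 genes, 244 were past the threshold with limma, 152 higher and 92 lower in tuft cells, and 1606 had an unadjusted p under 0.05. Among the calls, 58 had a whole group at 0 and 111 had no value at 0 (67 higher and 44 lower). The groups did not overlap at 2278 genes (18.6%, against 10% by chance). The authors' own deposited statistics called 179 genes (109 higher and 70 lower), of which 145 were shared with the present calls.

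Most calls in the pancreas were lost without any 1 of 5 of the 6 libraries. With limma and without 1 tuft library, 0 genes passed without tuft library 1 (1314 at an unadjusted p under 0.05), 0 without tuft library 2 (1390) and 1 without tuft library 3 (1316). Without non-tuft library 2 there were 10 calls (1558 unadjusted), without non-tuft library 3 there were 16 (1485), and without non-tuft library 1 there were 233 (1891), of which 142 were shared with the full set. Trpm5, Siglecf, Hck, Folr1 and Ly6g6f kept their calls in 3 of these 6 fits, the most of any gene named here.

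Tuft-cell core genes made the clearest rise in the pancreas, with 18 of 22 measured members higher and 0 lower (21 and 0 adjusted over the list alone). Their median difference was 5.21, with a camera adjusted p = 8.83e-34 (adjusted p = 0.166 with an estimated correlation). Siglecf, which encodes the stained Siglec F, had a mean of 6.68 ± 0.29 (SD, n = 3) in tuft libraries and was listed at 0 in all 3 non-tuft libraries (limma adjusted p = 0.000904). Siglecf was fixed in advance as a check of the sort. It is not on the tuft-cell core list, nor are Rac2, Ly6g6f and Folr1 below. Hck, a Src-family kinase, rose by 7.36 ± 0.7 (SE, adjusted p = 0.0019) and the adaptor Fyb by 6.63 ± 0.57 (adjusted p = 0.00109). The kinase Matk rose by 6.35 ± 0.52 (adjusted p = 0.00109). The channel gene Trpm5 rose by 6.24 ± 0.54 (adjusted p = 0.00109), and was 1, 0 and 0 in the 3 non-tuft libraries. It was the 1 member of 5 measured genes of taste transduction past the threshold (2 and 0 adjusted over the list alone; camera adjusted p = 0.0016, adjusted p = 0.242 with an estimated correlation). Dclk1 rose by 5.63 ± 0.67 (adjusted p = 0.00525). Pou2f3, a transcription factor of tuft cells, had a mean of 6.59 ± 0.22 in tuft libraries and was at 5.59, 0 and 0 in non-tuft libraries 1, 2 and 3, and its difference of 4.72 ± 1.3 was not past the threshold (adjusted p = 0.128). Rac2, a small GTPase, rose by 7.6 ± 0.72 (adjusted p = 0.0019). Ly6g6f (7.4 ± 0.28, SD) and the folate receptor gene Folr1 (7.26 ± 0.27, SD) were listed at 0 in all 3 non-tuft libraries, each with an adjusted p = 0.000445.

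Genes of eicosanoid metabolism were higher in the tuft libraries of the pancreas, with 7 of 12 members up and 0 down (7 and 0 adjusted over the list alone). The median was 3.14 (camera adjusted p = 2.98e-05, adjusted p = 0.287 with an estimated correlation). Alox5, the first enzyme of leukotriene synthesis, rose by 6.51 ± 0.92 (limma adjusted p = 0.0106), and its partner Alox5ap by 5.34 ± 0.68 (adjusted p = 0.00724). Hpgd, which breaks prostaglandins down, rose by 4.07 ± 0.53 (adjusted p = 0.00749). On the branch to PGD2, the cyclooxygenase gene Ptgs1 rose by 4.61 ± 0.63 (adjusted p = 0.00932), with 1.48, 0 and 0.46 in the non-tuft libraries. The PGD2 synthase gene Hpgds rose by 5.22 ± 0.98 (adjusted p = 0.0325), from 3.96, 0 and 0 to 6.54 ± 0.24 (SD). With 0.1 added before the log, neither Hpgds (0.102, and 0.00316 to 0.284 over all alternatives) nor Alox5 (0.0755, and 0.0103 to 0.218) was past the threshold. Ptges was not analysed here.

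Genes of the brush border and cytoskeleton rose at 4 of 12 members and fell at 0 (7 and 0 adjusted over the list alone), with a median of 1.83 (camera adjusted p = 3.12e-08, adjusted p = 0.166 with an estimated correlation). Tuba1a rose by 2.43 ± 0.32 (limma adjusted p = 0.00768), Espn by 4.22 ± 0.62 (adjusted p = 0.0128), the keratin gene Krt8 by 2.94 ± 0.45 (adjusted p = 0.0142) and Avil by 6.2 ± 1.08 (adjusted p = 0.0241). Type 2 cytokine and neuropeptide genes rose at 1 of 5 members, Il17rb (2 and 0 adjusted over the list alone; median 2.26, camera adjusted p = 0.0213, adjusted p = 0.242 with an estimated correlation), and the list kept its call in 2 of 6 fits without a library (highest 0.117). Il17rb rose by 4 ± 0.71 (limma adjusted p = 0.0272) and kept its call in 0 of 6 fits without a library (0.0563 to 0.263). Epcam was 9.99 ± 0.13 (SD) in tuft and 9.04 ± 0.61 in non-tuft libraries, a difference of 0.95 ± 0.35 that was not past the threshold (adjusted p = 0.26). Kras differed by −0.87 ± 0.67 (adjusted p = 0.638).

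Acinar genes were lower in the tuft libraries, with 0 of 20 members higher and 15 lower (0 and 19 adjusted over the list alone) and a median of −5.6 (camera adjusted p = 5.39e-26, adjusted p = 0.242 with an estimated correlation). The colipase gene Clps fell by 7.12 ± 0.71 (limma adjusted p = 0.00232), from 13.28 ± 1.46 to 6.16 ± 0.92 (SD), and the carboxypeptidase gene Cpa2 fell by 8.27 ± 1.1 (adjusted p = 0.00814). The acinar transcription factor gene Ptf1a, whose promoter drives Cre in these mice, was 5.5 ± 0.71 in non-tuft libraries and listed at 0 in all 3 tuft libraries (adjusted p = 0.0047). Looked at after the data were seen, the acinar list had a median level of 8.35 in non-tuft library 1 against 12.06 and 12.1 in libraries 2 and 3, and 19 of its 20 members were lowest there. The tuft-cell core list had medians of 2.77, 0.36 and 0.56, with 17 of 22 members highest in library 1 and 1 lowest. Endocrine genes fell at 5 of 17 members and rose at 1 (12 and 1 adjusted over the list alone), with a median of −3.56 (camera adjusted p = 1.11e-08, adjusted p = 0.166 with an estimated correlation). The islet hormone gene Ppy fell by 10.04 ± 0.78 (adjusted p = 0.000918) and Sst fell by 7.78 ± 0.57 (adjusted p = 0.000861). Pax6 fell by 4.41 ± 0.72 (adjusted p = 0.018). The riser was Sct, the secretin gene, with 3.27 ± 0.69 (adjusted p = 0.0498; chosen after its values were seen), which was not past the threshold with the number as a block (0.0843, with 0.0377 to 0.279 over all alternatives).

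Among lists for other cell types in the pancreas, fibroblast genes were lower as a list, with 1 of 4 past the threshold, Sparc, which fell by 4.73 ± 0.66 (limma adjusted p = 0.0104), and 0 up and 1 down adjusted over the list alone. Their median was −2.66 (camera adjusted p = 0.00348, adjusted p = 0.342 with an estimated correlation), and the call was lost without non-tuft library 3 (0.0762). Pan-leukocyte genes were higher as a list (median 1, camera adjusted p = 0.00928, adjusted p = 0.442 with an estimated correlation), with 1 of 10 past the threshold, Rac2 (1 and 0 adjusted over the list alone), and this list kept its call in 3 of 6 fits without a library (highest 0.161, lost without non-tuft libraries 1 and 2 and tuft library 2). Mast cell genes were also higher as a list, with 0 of 4 past the threshold (1 and 0 adjusted over the list alone; median 2.28, camera adjusted p = 0.00928, adjusted p = 0.404 with an estimated correlation), as were lymphocyte genes, with 1 of 5, Cd79b (1 and 0 adjusted over the list alone; median 2.09, camera adjusted p = 0.0298, adjusted p = 0.404 with an estimated correlation). Each kept its call in 3 of 6 fits without a library (highest 0.089 and 0.155; the first was lost without non-tuft libraries 2 and 3 and tuft library 1, the second without non-tuft libraries 1 and 2 and tuft library 2). Ductal genes were higher as a list although the 1 of 12 past the threshold, Ambp, fell (4 up and 1 down adjusted over the list alone; median 0.72, camera adjusted p = 0.0247, adjusted p = 0.436 with an estimated correlation), and the list kept its call in 2 of 6 fits without a library (highest 0.18). Rac2 was at 8.54 ± 0.3 (SD) in the tuft libraries, while the median of 8 other abundant leukocyte transcripts was 2.25; the highest of these, Cd52, was at 0, 5.46 and 4.68 in tuft libraries 1, 2 and 3. Ptprc, which encodes Cd45, was at 3.07, 5.72 and 5.68 in the tuft and 0, 0 and 4.57 in the non-tuft libraries, and its difference of 3.3 ± 1.27 was not past the threshold (adjusted p = 0.294).

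**Figure D1:**
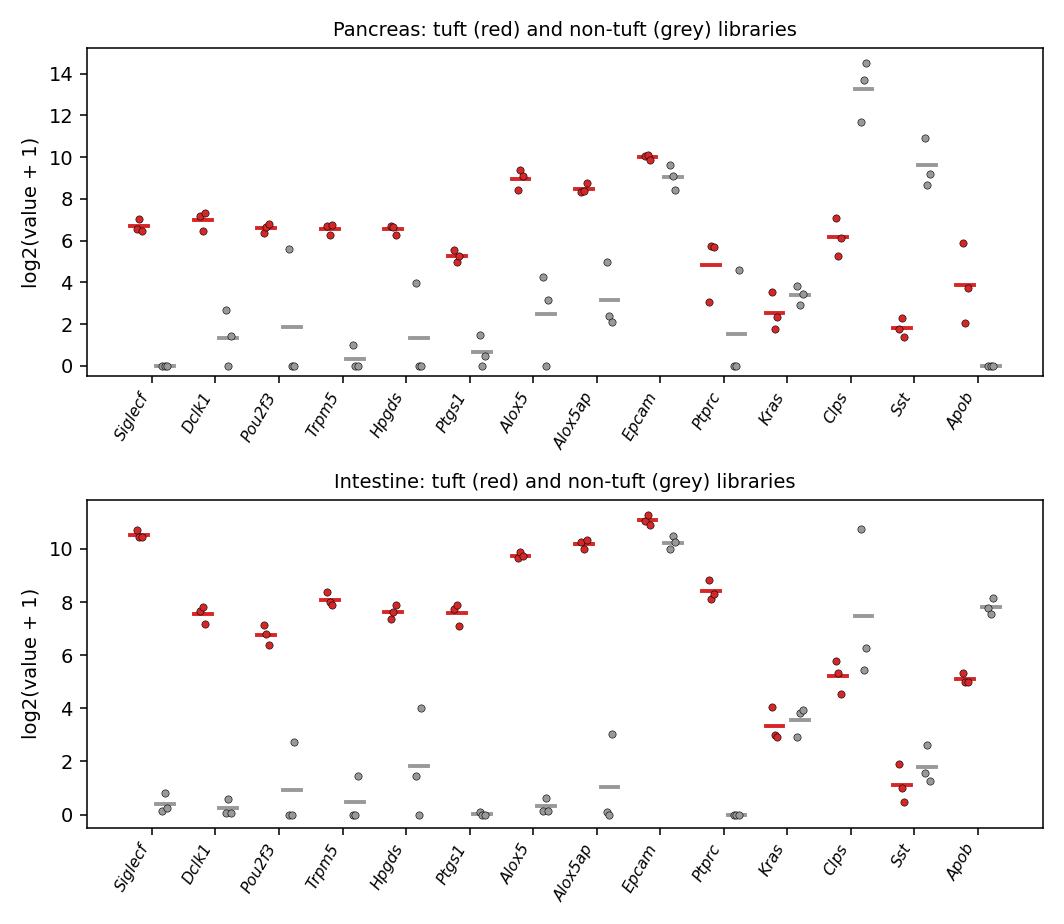
Log2 values of 14 genes in each library of the pancreas and the intestine, with tuft and non-tuft libraries as points and the group mean as a bar. Siglecf is at 0 in all 3 pancreatic non-tuft libraries.

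The comparison in the wild-type intestine asked the same of normal small-intestinal tuft cells. Their tuft-cell genes rose, with most of the measured taste-signalling and eicosanoid genes, and most genes of absorptive enterocytes fell, with some of goblet cells (5 of 11) and of dividing cells (3 of 15). Of 11132 genes, 1752 were past the threshold with limma (887 higher and 865 lower, or 876 and 887 with median-of-ratios scaling), and 1056 of these had no value at 0 (525 higher and 531 lower). The groups did not overlap at 3820 genes (34.3%, against 10% by chance). The authors' deposited statistics called 1508 (769 higher and 739 lower), of which 1395 were shared. Without 1 library the count was 1049 to 1366, with the largest losses without tuft library 2 (1049), non-tuft library 1 (1074) and non-tuft library 3 (1117).

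All 23 measured tuft-cell core genes rose in the intestine (23 and 0 adjusted over the list alone), with a median of 7.21 (camera adjusted p = 1.18e-28, adjusted p = 0.102 with an estimated correlation). Hck rose by 11.52 ± 0.26 (limma adjusted p = 4.48e-07), Rac2 by 10.53 ± 0.31 (adjusted p = 1.46e-06) and Siglecf by 10.14 ± 0.31 (adjusted p = 1.46e-06). Siglecf went from 0.39 ± 0.36 to 10.53 ± 0.16 (SD). Siglecf, a check of the sort, and Rac2 are not on the tuft-cell core list. Dclk1 rose by 7.3 ± 0.41 (adjusted p = 3.28e-05) and Pou2f3 by 5.86 ± 0.75 (adjusted p = 0.0017). Taste-transduction genes rose at 5 of 8 members and fell at 0 (6 and 0 adjusted over the list alone), with a median of 4.19 (camera adjusted p = 0.000484, adjusted p = 0.102 with an estimated correlation). Trpm5 rose by 7.61 ± 0.49 (adjusted p = 5.87e-05). Gng13 (5.81 ± 0.65, SD), the gustducin gene Gnat3 (5.15 ± 0.2) and the succinate receptor gene Sucnr1 (3.95 ± 0.61) were listed at 0 in all 3 non-tuft libraries, with adjusted p = 0.000423, 0.000547 and 0.00325. Plcb2, chosen after its values were seen, rose by 4.43 ± 0.67 (adjusted p = 0.00334).

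Eicosanoid genes rose at 6 of 11 members and fell at 0 in the intestine (6 and 1 adjusted over the list alone), with a median of 5.63 (camera adjusted p = 0.000699, adjusted p = 0.102 with an estimated correlation). Alox5 rose by 9.45 ± 0.31 (limma adjusted p = 1.9e-06), Alox5ap by 9.15 ± 0.74 (adjusted p = 0.000217), Ptgs1 by 7.55 ± 0.41 (adjusted p = 2.86e-05) and Ltc4s by 5.63 ± 0.49 (adjusted p = 0.00034). Hpgds rose by 5.81 ± 0.88 (adjusted p = 0.00347), to 7.63 ± 0.27 (SD) from 1.44, 0 and 4.02. It was not past the threshold without non-tuft library 1 (0.0537) or tuft library 3 (0.0509), with 0.00204 to 0.0537 over all alternatives. Type 2 cytokine and neuropeptide genes rose at 4 of 7 members (4 and 0 adjusted over the list alone), with a median of 2.07 (camera adjusted p = 0.0151, adjusted p = 0.145 with an estimated correlation). The cytokine genes Il25 (4.7 ± 1.32, SD, adjusted p = 0.00413) and Tslp (3.5 ± 0.59, adjusted p = 0.00544) were listed at 0 in all 3 non-tuft libraries, and Il17rb rose by 6.17 ± 0.7 (adjusted p = 0.00103). Chat, the acetylcholine synthase gene, was at 5.98 ± 0.31 (SD) and listed at 0 in all 3 non-tuft libraries (adjusted p = 0.000194). Il25 was not analysed here in the pancreas, and Ptges in neither tissue.

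Brush and cytoskeleton genes went both ways in the intestine, with 6 of 12 higher and 2 lower (7 and 3 adjusted over the list alone) and a median of 1.68 (camera adjusted p = 0.00496, adjusted p = 0.175 with an estimated correlation). This list was not past the threshold without tuft library 3 (0.0643). Krt18 rose by 6.58 ± 0.21 (limma adjusted p = 1.85e-06) and Avil by 7.68 ± 0.5 (adjusted p = 6.72e-05), and Pls1 fell by 2.6 ± 0.31 (adjusted p = 0.00136). The other faller was Eps8, chosen after its values were seen, with −2.23 ± 0.45 (adjusted p = 0.0124, and 0.00948 to 0.07 over all alternatives, the highest without non-tuft library 1). Epcam rose by 0.85 ± 0.21 (adjusted p = 0.0272), kept in 1 of 6 fits without a library (0.0386 to 0.152), and not past the threshold without the trend (0.182). Ptprc was at 8.42 ± 0.36 (SD) and listed at 0 in all 3 non-tuft libraries (adjusted p = 7.32e-06). With Rac2 it was among 2 of 4 pan-leukocyte genes that rose (3 and 0 adjusted over the list alone; median 5.06, camera adjusted p = 0.000699, adjusted p = 0.102 with an estimated correlation). Rac2 was at 11.08 ± 0.31 (SD), while the median of 6 other abundant leukocyte transcripts, 4 of them myeloid, was 1.66; the 2 pan-leukocyte ones were at 1.58 (Cd37) and 1.7 (Coro1a). Kras differed by −0.23 ± 0.54 (adjusted p = 0.803).

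Absorptive enterocyte genes fell at 13 of 15 members and rose at 0 (14 and 1 adjusted over the list alone), with a median of −3.21 (camera adjusted p = 7.77e-10, adjusted p = 0.118 with an estimated correlation). The apolipoprotein gene Apob fell by 2.71 ± 0.27 (limma adjusted p = 0.000551) and the alkaline phosphatase gene Alpi by 4.29 ± 0.49 (adjusted p = 0.00108). Goblet genes fell at 5 of 11 members (0 and 5 adjusted over the list alone), with a median of −4.11 (camera adjusted p = 0.000645, adjusted p = 0.232 with an estimated correlation). Spink4 fell by 5.93 ± 0.74 (adjusted p = 0.00155). Guca2a fell by 4.11 ± 0.86 (adjusted p = 0.0137), Agr2 fell by 4.57 ± 1.04 (adjusted p = 0.0192), Muc2 fell by 4.25 ± 1.05 (adjusted p = 0.0276), and Tff3, chosen after its values were seen, fell by 4.56 ± 1.2 (adjusted p = 0.0365). Guca2a kept its call in 2 of 6 fits without a library, and Agr2, Muc2 and Tff3 in 1 of 6 (highest adjusted p 0.105, 0.123, 0.141 and 0.194). Proliferation genes fell at 3 of 15 members (0 and 7 adjusted over the list alone), with a median of −2 (camera adjusted p = 0.000699, adjusted p = 0.117 with an estimated correlation). Acinar genes, the markers of the pancreas, were lower as a list here too, with 0 of 15 past the threshold (0 and 0 adjusted over the list alone; median −0.67, camera adjusted p = 0.0142, adjusted p = 0.398 with an estimated correlation). Ccnb2 was at 4.8 ± 1.05 (SD) in non-tuft libraries and listed at 0 in all 3 tuft libraries (adjusted p = 0.00232).

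The changes with the tuft label were then set side by side in the 9963 genes that both tables held. Of these, 106 rose in both tissues, against 12.2 if the calls were independent, and 4 fell in both (3.2 if independent). Genes higher in pancreatic and lower in intestinal tuft cells numbered 4 (10 if independent), and 0 went the other way (3.9 if independent). Of the 190 pancreatic calls among them, 88.9% had the same sign in the intestine. Across genes, which are not independent replicates, the correlation of the changes was r = 0.32 and rho = 0.22.

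**Figure D2:**
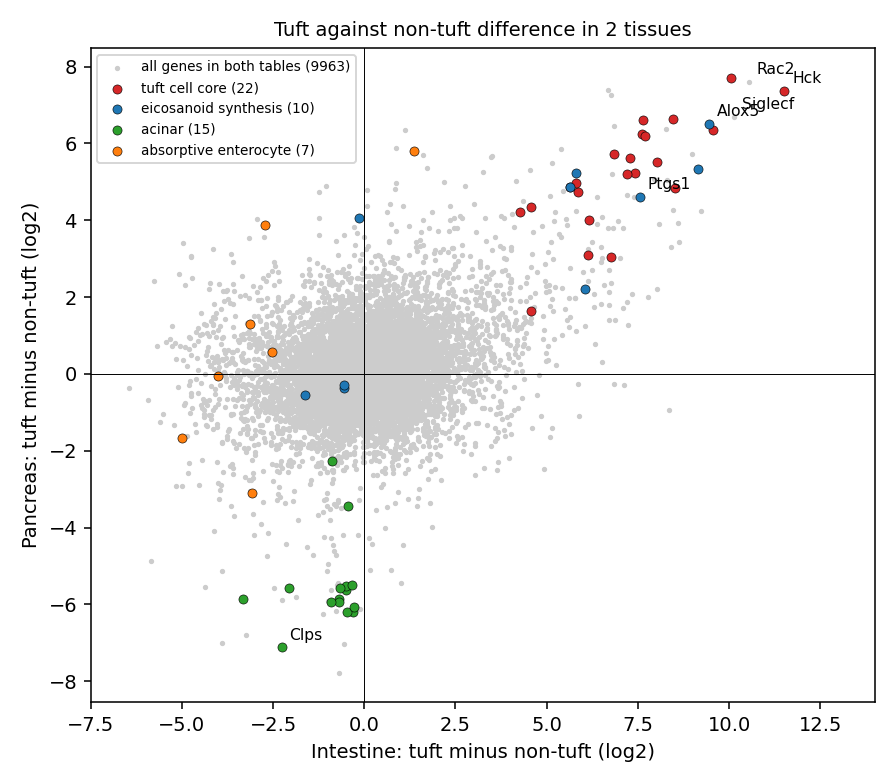
Difference between tuft and non-tuft libraries (log2) in the intestine (x axis) and the pancreas (y axis), 1 point per gene in both tables, with 4 gene lists coloured. Siglecf, Rac2, Hck, Alox5 and Ptgs1 lie above 0 on both axes, and Clps lies below 0 in the pancreas.

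Whether the tuft change itself differed between the tissues was tested as the change in the pancreas minus that in the intestine, in the same 9963 genes. As a list, tuft-cell genes rose by less in the pancreas than in the intestine with camera (adjusted p = 8.62e-07), with 4 of 22 members past the threshold, but not with an estimated correlation (adjusted p = 0.318). Of 15 acinar genes in both tables, 9 had a lower tuft change in the pancreas than in the intestine. The tuft change of 3 of 7 absorptive enterocyte genes was higher in the pancreas, where 1 of the 7, Fabp1, rose. Tissue and genotype change together here, so a difference belongs to KC pancreas against wild-type intestine. Each tuft change is also taken against the non-tuft libraries of its own tissue, so what those held enters the difference. With limma, 475 genes were past the threshold (245 higher and 230 lower). Without 1 library the count was 270 to 563, with the largest losses without intestinal tuft library 1 (270), pancreatic tuft library 2 (285), intestinal tuft library 2 (288) and intestinal non-tuft library 3 (289). Of the 475 calls, 97 had a whole group at 0 and 236 had no value at 0 (118 higher and 118 lower).

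Tuft-cell core genes were lower in this difference at 4 of 22 members and higher at 0 (6 and 0 adjusted over the list alone), with a median of −1.91 (camera adjusted p = 8.62e-07, adjusted p = 0.318 with an estimated correlation). The 4, chosen after their values were seen, were Hck (−4.15), Cd24a (−3.71), Matk (−3.21) and Plcg2 (−3.02). Hck was not past the threshold with 0.1 added before the log (0.226, with 0.000146 to 0.226 over all alternatives), and Plcg2 kept its call in 2 of 12 fits without a library (highest 0.118). Siglecf differed by −3.45 ± 0.51 (limma adjusted p = 0.00292, and 0.00219 to 0.251 over all alternatives, the highest with 0.1 added before the log). Ptgs1 differed by −2.93 ± 0.71 (adjusted p = 0.0319), kept in 3 of 12 fits without a library (highest 0.0961). It was lost with 0.1 added (0.121) and with the number as a block. Differences at Dclk1 (−1.67, adjusted p = 0.306), Trpm5 (−1.37, adjusted p = 0.33), Pou2f3 (−1.13, adjusted p = 0.79), Hpgds (−0.58, adjusted p = 0.892), Epcam (0.11, adjusted p = 0.93) and Kras (−0.63, adjusted p = 0.761) were not past the threshold. Ptprc differed by −5.12 ± 1.47 (adjusted p = 0.0673), and passed with the number as a block (0.0368, with 0.0348 to 0.2 over all alternatives). Past the threshold, the keratin gene Krt23 made the largest negative difference, −9.3 ± 0.77 (adjusted p = 4.64e-05), and the glucuronosyltransferase gene Ugt1a7c the largest positive, 8.38 ± 1.53 (adjusted p = 0.00867).

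Acinar genes differed at 9 of 15 members, all negative (12 adjusted over the list alone; median −5.03, camera adjusted p = 1.49e-11, adjusted p = 0.275 with an estimated correlation). Endocrine genes were negative as a list, with 1 of 11 past the threshold, Sst, at −7.1 ± 0.91 (0 and 1 adjusted over the list alone; median −2.2, camera adjusted p = 0.0108, adjusted p = 0.566 with an estimated correlation), and the call was lost without intestinal non-tuft library 2 or 3 (highest 0.0834). Absorptive enterocyte genes were positive at 3 of 7 members (6 adjusted over the list alone; median 3.96, camera adjusted p = 4.92e-06, adjusted p = 0.127 with an estimated correlation), namely Apob (6.6), Fabp1 (4.44) and Slc2a2 (3.96), chosen after their values were seen. Slc2a2 was lost with 0.1 added (0.292, with 0.0212 to 0.292 over all alternatives). In the pancreas alone, Fabp1 rose and was the 1 of these 7 members past the threshold (list median 0.57, from −3.11 to 5.81). It kept that call in 1 of 6 fits without a library. The difference at Fabp1 was thus not only a fall in the intestine. Goblet genes were positive at 1 of 8, Spink4 (5.24), also chosen after its values were seen and kept in 3 of 12 fits without a library (4 adjusted over the list alone; median 4.83, camera adjusted p = 0.00184, adjusted p = 0.275 with an estimated correlation).

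Macrophages were compared first with and without LPS, both with vehicle, as the background for the PGD2 comparisons. LPS raised all 24 interferon-stimulated genes and most M1-type (14 of 15), chemokine (12 of 13) and cytokine genes (9 of 10, with 1 lower), and all 20 genes of cell division fell. Of 8995 genes, 5691 were past the threshold with limma (2587 higher and 3104 lower, or 2884 and 2787 with median-of-ratios scaling), and 2069 of these differed by a log2 of at least 1 (1009 higher and 1060 lower). The groups did not overlap at 6093 genes (67.7%, against 10% by chance). Leaving out 1 library gave 5133 to 5700.

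Interferon-stimulated genes rose at 24 of 24 members with LPS (24 and 0 adjusted over the list alone; median 5.48, camera adjusted p = 2e-14, adjusted p = 0.195 with an estimated correlation), among them Stat1, by 3.3 ± 0.12 (limma adjusted p = 3.02e-09). M1 polarization genes rose at 14 of 15 (14 and 0 adjusted over the list alone; median 5.82, camera adjusted p = 8e-09, adjusted p = 0.0401 with an estimated correlation), among them Nos2, by 8.64 ± 0.32 (adjusted p = 3.2e-09). Inflammatory chemokine genes rose at 12 of 13 (12 and 0 adjusted over the list alone; median 4.37, camera adjusted p = 4.76e-06, adjusted p = 0.143 with an estimated correlation), and Ccl5 made the largest rise of all genes past the threshold, 11.65 ± 0.28 (adjusted p = 1.96e-10). LPS cytokine genes rose at 9 of 10 (9 and 1 adjusted over the list alone; median 3.19, camera adjusted p = 0.000162, adjusted p = 0.195 with an estimated correlation). Il1b rose by 9.61 ± 0.22 (adjusted p = 1.27e-10) and Tnf by 2.25 ± 0.27 (adjusted p = 3.3e-05), while Tnfsf9, chosen after its values were seen, fell by 0.5 ± 0.09 (adjusted p = 0.000597). Il6 (3.8 ± 1.08, SD) and Il12b (3.08 ± 1.31) were listed at 0 in all 3 libraries without LPS. Arg1 rose by 5.26 ± 0.6 (adjusted p = 2.18e-05) and Il10 by 3.01 ± 0.15.

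Proliferation genes fell at 20 of 20 members with LPS (0 and 20 adjusted over the list alone; median −4.71, camera adjusted p = 2e-14, adjusted p = 0.00959 with an estimated correlation), among them Ccna2, by 6.37 ± 0.11 (limma adjusted p = 1.78e-11). NRF2 and oxidative stress genes rose at 17 of 21 members (17 and 2 adjusted over the list alone; median 1.02, camera adjusted p = 0.000866, adjusted p = 0.266 with an estimated correlation), among them Hmox1, by 3.25 ± 0.24 (adjusted p = 7.13e-07). Tkt (−0.86) and Gclc (−0.57), chosen after their values were seen, fell. Eicosanoid genes rose at 3 of 13 and fell at 6 (3 and 6 adjusted over the list alone), with a median of −0.33 (camera adjusted p = 0.683). Ptges rose by 7.71 ± 0.16 (adjusted p = 7.1e-11) and Ptgs2 by 5.82 ± 0.53 (adjusted p = 4.3e-06), whereas Hpgds fell by 2.06 ± 0.16 (adjusted p = 9.68e-07) and Pparg by 1.61 ± 0.22 (adjusted p = 7.46e-05).

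What PGD2, the product of the Hpgds enzyme, did to macrophages without LPS was asked next. Most genes of the antioxidant response that NRF2 controls rose, with most of cholesterol synthesis and glycolysis. The measured genes of cell division fell, with 7 of 13 chemokine genes and 8 of 24 interferon-stimulated genes. Of 8995 genes, 2912 were past the threshold with limma (1450 higher and 1462 lower, or 1260 and 1705 with median-of-ratios scaling), and 699 of these differed by a log2 of at least 1 (312 higher and 387 lower). The groups did not overlap at 4319 genes (48%, against 10% by chance). Fits that left out 1 library called 2366 to 3131. The PGD2 receptor genes Ptgdr and Ptgdr2 were not analysed here.

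NRF2 and oxidative stress genes rose at 19 of 21 members with PGD2 alone (19 and 0 adjusted over the list alone; median 2.39, camera adjusted p = 7.24e-17, adjusted p = 0.0471 with an estimated correlation). The glutathione transferase gene Gsta3 made the largest rise, 5.8 ± 0.19 (limma adjusted p = 7.49e-08), from 0.21, 0.1 and 0 to 5.91 ± 0.08 (SD). Gclm rose by 4.37 ± 0.28 (adjusted p = 1.97e-06), the heme oxygenase gene Hmox1 by 4.23 ± 0.24 (adjusted p = 1.02e-06) and Nqo1 by 3.52 ± 0.16 (adjusted p = 2.8e-07). Mgst2 was at 5.68 ± 0.46 (SD) and listed at 0 in all 3 vehicle libraries (adjusted p = 5.4e-07). Cholesterol synthesis genes rose at 15 of 19 members (15 and 0 adjusted over the list alone; median 0.88, camera adjusted p = 5.02e-06, adjusted p = 0.539 with an estimated correlation), among them Mvd, by 1.14 ± 0.16 (adjusted p = 0.000329). Glycolysis and hypoxia genes rose at 12 of 17 (12 and 0 adjusted over the list alone; median 0.76, camera adjusted p = 4.17e-05, adjusted p = 0.539 with an estimated correlation), among them Slc2a1, by 1.37 ± 0.16 (adjusted p = 8.23e-05).

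Proliferation genes fell at 20 of 20 members with PGD2 alone (0 and 20 adjusted over the list alone; median −1.52, camera adjusted p = 5.78e-17, adjusted p = 0.00548 with an estimated correlation), among them Ccna2, by 1.9 ± 0.11 (limma adjusted p = 1.08e-06). Inflammatory chemokine genes fell at 7 of 13 (0 and 8 adjusted over the list alone; median −1.03, camera adjusted p = 0.0129, adjusted p = 0.539 with an estimated correlation), among them Ccl7, by 3.65 ± 0.57 (adjusted p = 0.000742), and Ccl12, by 2.63 ± 0.42 (adjusted p = 0.000835). Interferon-stimulated genes fell at 8 of 24 (0 and 8 adjusted over the list alone; median −0.85, camera adjusted p = 0.000525, adjusted p = 0.72 with an estimated correlation), among them Oas3, by 2.58 ± 0.32 (adjusted p = 0.000152). Tnf fell by 1 ± 0.27 (adjusted p = 0.016), and was not past the threshold without vehicle library 1 (0.0544), vehicle library 2 (0.0601) or PGD2 library 3 (0.0608), with 0.00251 to 0.064 over all alternatives. Arg1 rose by 2.59 ± 0.6 (adjusted p = 0.00716). Pparg fell by 1.42 ± 0.22 (adjusted p = 0.000581) and Hpgds by 0.82 ± 0.16 (adjusted p = 0.00222). Il1b (0.01 ± 0.22, adjusted p = 0.977), Nos2 (−0.04, adjusted p = 0.943) and Il10 (−0.06, adjusted p = 0.823) were not past the threshold, and Il6 and Il12b were listed at 0 in all 6 libraries.

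PGD2 after LPS was compared with vehicle after LPS, to ask whether PGD2 altered macrophages already turned toward the M1 state. Most antioxidant genes rose again, with most heat shock genes. Most interferon-stimulated genes fell (17 of 24), with 3 of 11 antigen presentation genes and 4 of 15 M1 genes, among them Nos2. Of 13 chemokine genes, 6 fell and 3 rose (Cxcl1, Cxcl2 and Cxcl3). With limma, 2166 genes were past the threshold (1209 higher and 957 lower), against 3606 (2010 higher and 1596 lower) with the number as a block and 1395 with only the 2 groups compared. Median-of-ratios scaling turned the balance to 1016 higher and 1183 lower. A log2 difference of at least 1 was found at 397 of the 2166 (154 higher and 243 lower). The groups did not overlap at 3489 genes (38.8%, against 10% by chance). Without 1 library the count was 1552 to 2181.

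Interferon-stimulated genes fell at 17 of 24 members with PGD2 after LPS (0 and 20 adjusted over the list alone; median −1.47, camera adjusted p = 3.99e-11, adjusted p = 0.294 with an estimated correlation), among them Stat1, by 1.46 ± 0.12 (limma adjusted p = 4.73e-05). Inflammatory chemokine genes fell at 6 of 13 and rose at 3 (6 and 3 adjusted over the list alone), and were not past the threshold as a list (median −0.8, camera adjusted p = 0.112, adjusted p = 0.571 with an estimated correlation). The chemokine gene Cxcl10 fell by 3.72 ± 0.59 (adjusted p = 0.00165), from 8.71 ± 0.36 to 4.99 ± 0.63 (SD), and Ccl12 by 3.77 ± 0.42 (adjusted p = 0.000248). Cxcl1 rose by 1.99 ± 0.42 (adjusted p = 0.00655). So did Cxcl2, by 2.18 ± 0.6 (adjusted p = 0.025), and Cxcl3, by 1.38 ± 0.42 (adjusted p = 0.0366), both chosen after their values were seen. Cxcl2 kept its call in 8 and Cxcl3 in 6 of 12 fits without a library (highest 0.0854 and 0.124), and with 0.1 added before the log Cxcl3 was not past the threshold (0.244). M1 polarization genes fell at 4 of 15 and rose at 1 (5 and 1 adjusted over the list alone; median −0.56, camera adjusted p = 0.0118, adjusted p = 0.294 with an estimated correlation). Nos2 fell by 1.93 ± 0.32 (adjusted p = 0.00198), from 8.68 ± 0.86 to 6.75 ± 0.09 (SD), and the riser was Ptgs2, chosen after its values were seen, with 2.17 ± 0.53 (adjusted p = 0.0148, and 0.00434 to 0.0572 over all alternatives, with 0.0524 without LPS and PGD2 library 2). Antigen presentation genes fell at 3 of 11, Psmb9, H2-K1 and H2-DMa (0 and 5 adjusted over the list alone; median −0.54, camera adjusted p = 0.00337, adjusted p = 0.294 with an estimated correlation). H2-DMa kept its call in 7 of 12 fits without a library (highest 0.118, without LPS and vehicle library 3), and with only the 2 groups compared neither H2-DMa (0.0504, with 0.0013 to 0.118 over all alternatives) nor H2-K1 (0.0594, with 0.00417 to 0.0594) was past the threshold.

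NRF2 and oxidative stress genes rose at 17 of 21 members after LPS (18 and 0 adjusted over the list alone; median 1.42, camera adjusted p = 6.52e-13, adjusted p = 0.185 with an estimated correlation), among them Gsta3, by 2.45 ± 0.19 (limma adjusted p = 3.56e-05). Heat shock genes rose at 10 of 11 (11 and 0 adjusted over the list alone; median 0.95, camera adjusted p = 2.11e-07, adjusted p = 0.294 with an estimated correlation), among them Hspa8, by 1.55 ± 0.13 (adjusted p = 5.49e-05). Macrophage identity genes fell at 8 of 16 (9 down and 1 up adjusted over the list alone; median −0.78, camera adjusted p = 0.000384, adjusted p = 0.294 with an estimated correlation), among them Mafb, by 0.96 ± 0.15 (adjusted p = 0.00163). Proliferation genes were not past the threshold as a list (median 0, camera adjusted p = 0.401), with 1 of 20 lower (0 and 1 adjusted over the list alone), Mcm5, by 0.8 ± 0.16 (adjusted p = 0.005). Il10 fell by 1.2 ± 0.15 (adjusted p = 0.000509). Arg1 differed by −1.51 ± 0.6 (adjusted p = 0.0939), and passed with the number as a block (0.0362) and without LPS and PGD2 library 1 (0.0368), with 0.0362 to 0.249 over all alternatives. Tnf (−0.06, adjusted p = 0.903), Il6 (0.99 ± 0.46, adjusted p = 0.151), Il1b (−0.36, adjusted p = 0.266), Il12b (−0.36, adjusted p = 0.705), Pparg (0.06, adjusted p = 0.877) and Hpgds (0.24, adjusted p = 0.288) were not past the threshold. Il6 passed without LPS and vehicle library 2 (0.0182, with 0.0182 to 0.457 over all alternatives).

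**Figure D3:**
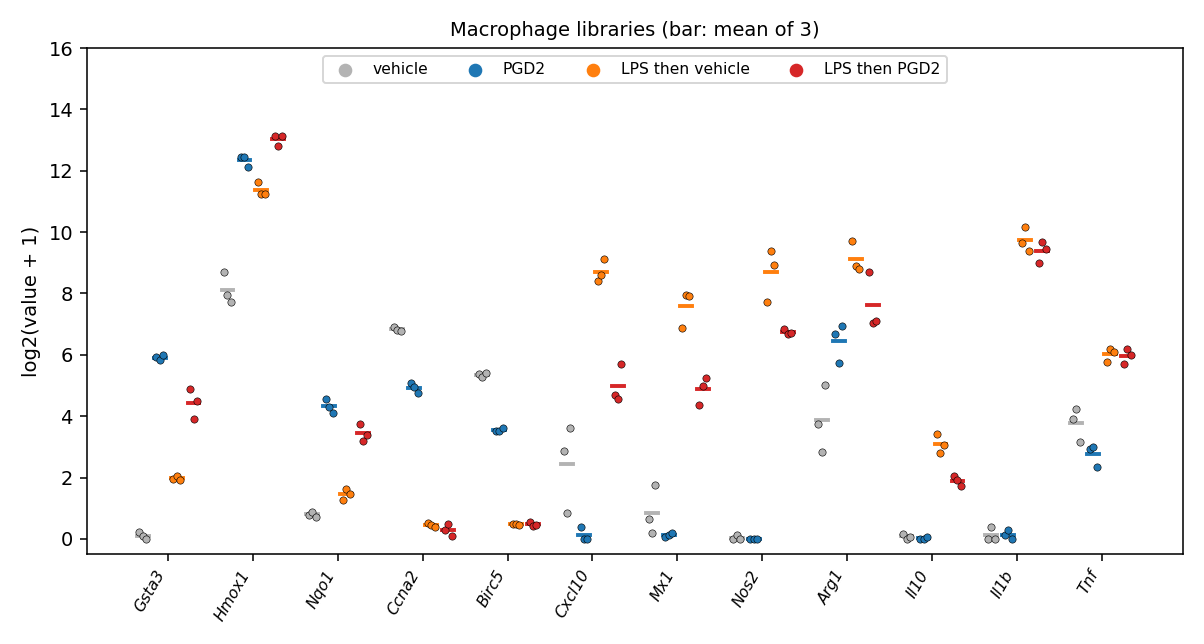
Log2 values of 12 genes in each of the 12 macrophage libraries, by group, with the group mean as a bar. Nos2 is at 8.68 with LPS and vehicle and 6.75 with LPS and PGD2 (means of 3 libraries).

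The genes that LPS raised and PGD2 then lowered numbered 591 (274.4 if the calls were independent), and those that LPS lowered and PGD2 then raised 585 (416.3 if independent). Both comparisons use the LPS and vehicle libraries, which by itself gives opposite changes. The covariance of the changes across genes was −0.202, against −0.03 from the shared libraries alone in 100 simulations. The correlation was r = −0.32, against −0.5 in those simulations, so only the covariance goes beyond what the shared libraries give. Without and after LPS, which share no library, PGD2 raised 442 genes in both (194.1 if independent) and lowered 242 in both (155.1). It raised without LPS and lowered after LPS 99 (153.4 if independent), and the reverse held for 118 (196.2).

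The interaction, the PGD2 change after LPS minus that without LPS, tested whether LPS altered the response to PGD2. PGD2 lowered nearly all proliferation genes by more without LPS than after it, and raised most NRF2 genes (14 of 21) by less after LPS. Its change was also lower after LPS at some of the cholesterol (7 of 19) and glycolysis genes (6 of 17). After LPS, PGD2 raised 0 of 19 cholesterol genes and lowered 1 (median 0.12, camera adjusted p = 0.919). It raised 3 of 17 glycolysis genes there and lowered 0 (median 0.06, camera adjusted p = 0.417). Arg1 and Nos2 moved downward and Cxcl2 upward in the interaction. With limma, 2302 genes were past the threshold (1296 higher and 1006 lower), against 3701 (1974 higher and 1727 lower) with the number as a block. Without 1 library the count was 1857 to 2481. Of the 2302 calls, 77 had a whole group at 0 and 2141 had no value at 0.

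Proliferation genes differed at 19 of 20 members in the interaction, all positive (19 adjusted over the list alone; median 1.44, camera adjusted p = 1.99e-14, adjusted p = 0.0095 with an estimated correlation). NRF2 genes differed at 14 of 21, all negative (16 adjusted over the list alone; median −1.04, camera adjusted p = 7.65e-08, adjusted p = 0.213 with an estimated correlation). Cholesterol synthesis genes differed at 7 of 19, all negative (9 adjusted over the list alone; median −0.64, camera adjusted p = 4.32e-05, adjusted p = 0.381 with an estimated correlation). Glycolysis and hypoxia genes did so at 6 of 17 (8 adjusted over the list alone; median −0.71, camera adjusted p = 0.00345, adjusted p = 0.432 with an estimated correlation). Heat shock genes were positive at 5 of 11 (5 and 0 adjusted over the list alone; median 0.79, camera adjusted p = 0.00505, adjusted p = 0.38 with an estimated correlation). M1 polarization genes were negative at 6 of 15 (6 adjusted over the list alone; median −0.75, camera adjusted p = 0.0162, adjusted p = 0.37 with an estimated correlation). Interferon-stimulated genes were negative at 7 and positive at 3 of 24 (10 and 4 adjusted over the list alone; median −0.84, camera adjusted p = 0.0419, adjusted p = 0.708 with an estimated correlation). PPAR and lipid handling genes were negative at 6 and positive at 1 of 15 (6 and 1 adjusted over the list alone; median −0.37, camera adjusted p = 0.0419, adjusted p = 0.37 with an estimated correlation). M2 polarization genes were negative at 2 of 13 (2 adjusted over the list alone), and were not past the threshold as a list (median −0.47, camera adjusted p = 0.0501, adjusted p = 0.381 with an estimated correlation). With the number as a block the interferon list (0.0596) and the PPAR list (0.081) were not past the threshold, and the M2 list was (0.025). Without 1 library the interferon list (highest 0.331) and the PPAR list (highest 0.0802) each kept the call in 7 of 12 fits.

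Tubb2b made the largest positive difference in the interaction, 3.99 ± 0.21 (limma adjusted p = 7.11e-06), and Ms4a4b the largest negative, −4.16 ± 0.19 (adjusted p = 4.05e-06). Arg1 differed by −4.1 ± 0.85 (adjusted p = 0.0058), Nos2 by −1.89 ± 0.45 (adjusted p = 0.0113) and Il10 by −1.15 ± 0.22 (adjusted p = 0.00373). With 0.1 added before the log Il10 was not past the threshold (0.14, with 0.00178 to 0.14 over all alternatives). Pparg differed by 1.47 ± 0.3 (adjusted p = 0.00579) and Hpgds by 1.07 ± 0.22 (adjusted p = 0.00568). Cxcl2 differed by 2.64 ± 0.86 (adjusted p = 0.0446), kept in 4 of 12 fits without a library (highest 0.0994). Tnf differed by 0.95 ± 0.38 (adjusted p = 0.097), and passed with the number as a block (0.0358, with 0.0177 to 0.195 over all alternatives). Il6 (0.99, adjusted p = 0.302), Il1b (−0.37, adjusted p = 0.417) and Il12b (−0.36, adjusted p = 0.795) were not past the threshold.

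**Figure D4:**
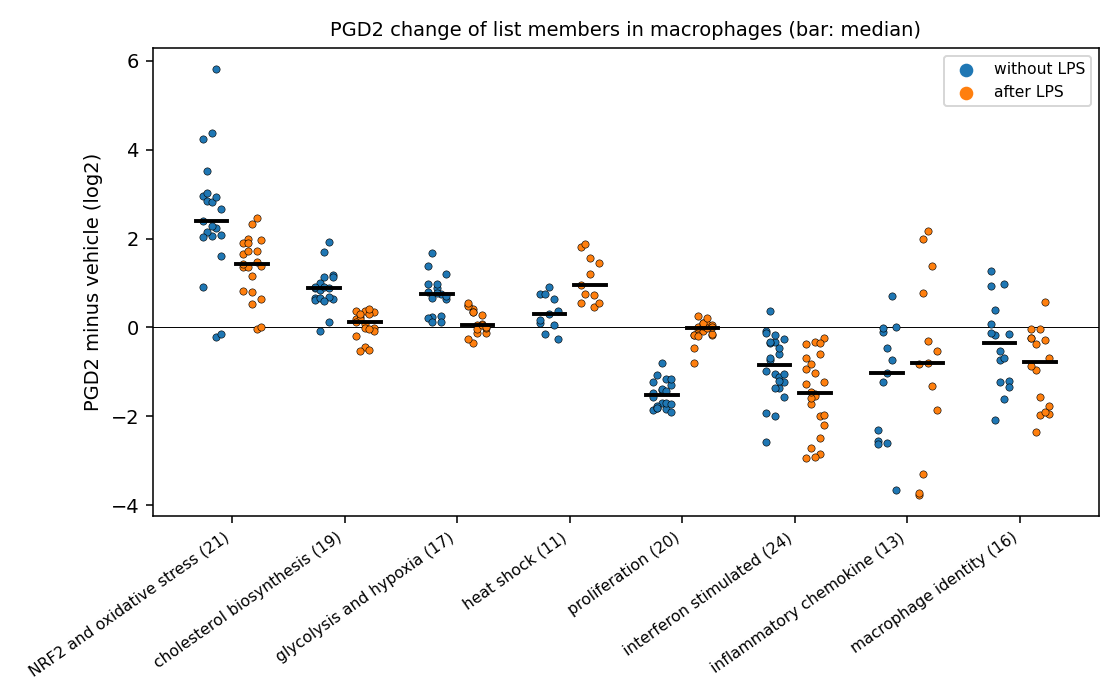
Change with PGD2 (log2) of the members of 8 gene lists, without LPS and after LPS, 1 point per gene and the median as a bar. The median of the proliferation list is −1.52 without and 0 after LPS, and that of the interferon list −0.85 without and −1.47 after LPS.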

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

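The explanations tested in this part, and the splits of the samples, were chosen after the results were seen; the interaction and the tissue difference themselves were planned.

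The response of macrophages to PGD2 differed with LPS, by the test of the interaction (PGD2 change after LPS minus that without LPS, limma). It passed the threshold at 2302 genes. Of 100 splits of the 12 libraries drawn without regard to their numbers, the real one included, 1 gave as many, and the highest other gave 1276. These splits exchange PGD2 and vehicle within an LPS arm. They ask whether PGD2 had any effect, not whether LPS altered it, so they cannot decide on chance for the interaction. The split that adds the PGD2 changes was not among those drawn. The libraries pair by number, which these splits do not keep. Of the 32 splits that swap PGD2 and vehicle only within same-number pairs, 2 gave as many, a share not under 0.05. Since 1 of the 32 always adds the PGD2 changes, these too cannot decide on chance, which is not excluded. The 2 were the real one and the one that swaps every pair of 1 LPS arm, which adds the PGD2 changes and gave 3329 from the structure of the samples. The highest of the rest gave 1123. With the number as a block these values were 3701, 4582 and 1527. The largest positive differences were at Tubb2b (3.99 ± 0.21, SE, adjusted p = 7.11e-06), Hmmr (3.55 ± 0.25, adjusted p = 3.22e-05), Akap2 (3.22 ± 1.02, adjusted p = 0.0404), Rgs1 (2.82 ± 0.61, adjusted p = 0.00772) and Cxcl2 (2.64 ± 0.86, adjusted p = 0.0446). Akap2 kept its call in 3 and Cxcl2 in 4 of 12 fits without a library, and with 0.1 added before the log neither Akap2 (0.0711, with 0.00961 to 0.0922 over all alternatives) nor Cxcl2 (0.0611, with 0.0012 to 0.0994) was past the threshold. The largest negative differences were at Ms4a4b (−4.16 ± 0.19, adjusted p = 4.05e-06), Arg1 (−4.1 ± 0.85, adjusted p = 0.0058), Pla2g7 (−3.73 ± 0.7, adjusted p = 0.00366), Clec4n (−3.64 ± 0.48, adjusted p = 0.000544) and Tgtp1 (−3.44 ± 0.45, adjusted p = 0.000498). Among the genes fixed in advance, Nos2 (−1.89), Il10 (−1.15), Pparg (1.47) and Hpgds (1.07) passed, and Il10 did not with 0.1 added before the log (0.14).

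Lists past the threshold in the interaction with camera had medians of 1.44 (proliferation), 0.79 (heat shock), −1.04 (NRF2), −0.64 (cholesterol synthesis), −0.71 (glycolysis and hypoxia), −0.75 (M1 polarization), −0.77 (endothelial), −0.84 (interferon), −0.37 (PPAR and lipid handling), −0.8 (prostaglandin receptors and transport) and −0.48 (macrophage identity). Only the proliferation list passed with an estimated correlation (adjusted p = 0.0095). Without 1 library, the interferon, PPAR and macrophage identity lists each kept their camera call in 7 of 12 fits (highest adjusted p 0.331, 0.0802 and 0.108). The prostaglandin list kept its call in 10 of 12 (highest 0.104).

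PGD2 raised NRF2 genes by less after LPS than without it (median interaction −1.04). The median lay at percentile 0 of 10000 random lists matched on the mean level over the 12 libraries, which ran from −0.49 to 0.57. This argues only against quantile normalization that moved all genes of this mean level alike. The lists were not matched on the level in each group, so other effects of normalization stay open. That LPS brought these genes closer to a level that PGD2 alone already reaches may explain part of the smaller rise, and stays open. LPS by itself raised 13 of the 14 members called in the interaction. Their level with LPS and PGD2 differed from that with PGD2 alone at 6 of the 14 (4 below and 2 above, −1.48 to 0.68), which goes against a shared level for these 6 and decides nothing for the rest.

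PGD2 lowered proliferation genes by a median of 1.52 without LPS and by 0 after LPS (median interaction 1.44). The interaction lay at percentile 100 of matched lists (−0.49 to 0.53). Those cannot decide on normalization here, since they were matched on the mean over all libraries. The proliferation list had a median change of −4.71 with LPS and a median level of 0.91 with LPS and vehicle, so its level differed widely between groups. A lack of room above the floor of the values at 0 is argued against as the whole cause. Whether the transcripts left after LPS could still fall by the same fold was not tested. At 8 members the same linear fold would have given at least 50% of the fall without LPS, and their observed change lay above the expected one by a median of 0.81, beyond 2 SE at 7 of the 8 (all but Mcm5). The other 12 were near the floor after LPS, with an expected fall of −0.33 in the median. Their observed change lay above it by a median of 0.3, beyond 2 SE at 6 of the 12. The SE, here and at the 8, is that of the observed change alone and leaves out the error of the expected one. At the 12 a lack of room and a lost response to PGD2 cannot be told apart.

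The tuft change differed between the tissues at 475 genes (pancreas minus intestine, limma). Of 100 splits, the real one included, 6 gave as many. They exchange the tuft and non-tuft names within each tissue, so they ask for any tuft change and not for an equal one in both. The splits therefore cannot decide on chance, which is not excluded for the number. The highest other gave 1337, from the split that swaps the tuft and non-tuft names in 1 tissue and so adds the changes of both, which points to the structure of the samples. Tissue, genotype and the content of the non-tuft libraries cannot be separated in this design, and each stays open, untested. Pancreatic non-tuft library 1 held the tuft-cell core list at a median of 2.77, against 0.36 and 0.56 in libraries 2 and 3. That lowers the pancreatic tuft change. The list kept its call with camera in 12 of 12 fits without a library (highest adjusted p = 0.000258). The largest positive differences were at Ugt1a7c (8.38 ± 1.53, SE, adjusted p = 0.00867), Gsta2 (8.19 ± 1.86, adjusted p = 0.0242), Sprr2a3 (7.8 ± 1.71, adjusted p = 0.0204), Ces2c (7.68 ± 1.6, adjusted p = 0.0166) and Cmbl (7.4 ± 1.03, adjusted p = 0.00244). The largest negative were at Krt23 (−9.3 ± 0.77, adjusted p = 4.64e-05), Rprml (−7.41 ± 1.23, adjusted p = 0.00527), Hmgn3 (−7.39 ± 0.7, adjusted p = 0.000113), Car7 (−7.11 ± 1.34, adjusted p = 0.0107) and Sst (−7.1 ± 0.91, adjusted p = 0.00152). Car7 was not past the threshold with 0.1 added before the log (0.0563, with 0.0065 to 0.0563 over all alternatives). Gsta2 kept its call in 7 and Sprr2a3 in 9 of 12 fits without a library. Siglecf (−3.45) and Ptgs1 (−2.93) passed among the genes fixed in advance. So did, chosen after their values were seen, Cd24a (−3.71), Matk (−3.21), Hck (−4.15), Plcg2 (−3.02), Apob (6.6), Fabp1 (4.44), Slc2a2 (3.96) and Spink4 (5.24). Of these, Plcg2 kept its call in 2, Spink4 in 3 and Slc2a2 in 5 of 12 fits without a library. With 0.1 added before the log, Siglecf (0.251, with 0.00219 to 0.251 over all alternatives), Ptgs1 (0.121, with 0.0222 to 0.121), Hck (0.226, with 0.000146 to 0.226), Plcg2 (0.106, with 0.0205 to 0.118) and Slc2a2 (0.292, with 0.0212 to 0.292) were not past the threshold.

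Lists past the threshold in the tissue difference with camera had medians of −1.91 (tuft core), −3.13 (cholinergic and synaptic), −5.03 (acinar), −2.2 (endocrine), 3.96 (absorptive enterocyte) and 4.83 (goblet), and 0 of them passed with an estimated correlation.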

How the results depend on the processing

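The fits of only genes with no value at 0 and of genes with a mean log2 of at least 1 were chosen after seeing the data; the other alternatives were planned. Counts of genes stayed within 1.5 times the reported count without the trend, with a mean value of at least 5, with median-of-ratios scaling, with repeated quantile normalization, and with a mean log2 of at least 1. Median-of-ratios scaling turned the balance of calls to 1016 higher and 1183 lower with PGD2 after LPS, 2884 and 2787 with LPS, and 876 and 887 in the intestine. The exceptions follow, and the cause was not tested except where named. With 0.1 added before the log, the pancreas had 155 calls. Only genes with no value at 0 gave 127 in the pancreas and 265 in the tissue difference, from fewer genes tested. The block gave 3606 with PGD2 after LPS and 3701 in the interaction, and only the 2 groups compared gave 1395 with PGD2 after LPS, from fewer samples.

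Leaving out 1 library, which also means fewer samples, gave 0 to 233 calls in the pancreas (244 with all), 1049 to 1366 in the intestine (1752) and 270 to 563 in the tissue difference (475). The pancreas had 0 without tuft library 1 or 2. PGD2 after LPS ranged from 1552 to 2181, the interaction from 1857 to 2481, PGD2 alone from 2366 to 3131 and LPS from 5133 to 5700.

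With an estimated correlation, the lists past the threshold fell from 15 to 0 in the pancreas, from 13 to 0 in the intestine, from 6 to 0 in the tissue difference, from 11 to 2 with LPS, from 7 to 2 with PGD2 alone, from 6 to 0 with PGD2 after LPS and from 11 to 1 in the interaction. In place of camera, fry gave 7 in the pancreas, 2 in the tissue difference, 18 with LPS, 11 with PGD2 alone and 10 with PGD2 after LPS. Without 1 library the pancreas had 8 to 14 lists. In the intestine, the estimated correlation was 0 for the eicosanoid, −0.03 for the pan-leukocyte and −0.17 for the endothelial list. With it, their camera adjusted p still went from 0.000699, 0.000699 and 0.00455 to 0.102, 0.102 and 0.117. These estimates lie below the preset correlation, so correlated genes do not account for these losses. For other lists the estimate was higher, such as 0.85 for acinar genes in the pancreas. There the cause of the loss was not tested.

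Of 321 results for named genes, 307 kept their direction and side of the threshold without the trend, 295 with 0.1 added, 320 with median-of-ratios scaling and 311 with the block. Calls gained or lost with the block were those of Muc6 (0.0504), Tnfrsf19 (0.0843) and Sct (0.0843) in the pancreas, Mcm5 in the intestine (0.0684), Ptgs1 (0.0614), Plcg2 (0.106), Slc2a2 (0.0776) and Ptprc (0.0368) in the tissue difference, Arg1 with PGD2 after LPS (0.0362) and Tnf in the interaction (0.0358). The intestinal numbers gave no sign of pairing (r of −0.016 to 0.034 for the same number, −0.04 to 0.034 for others).

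Reversed values were all of results not past the threshold. Without 1 library, Il1b ran from −0.07 to 0.14 with PGD2 alone. With PGD2 after LPS, Tnf ran from −0.19 to 0.07, Pparg from −0.07 to 0.26 and Il12b from −1.06 to 0.23, as it did in the interaction. In the tissue difference Epcam ran from −0.21 to 0.4, Pou2f3 from −2.06 to 0.73 and Hpgds from −1.68 to 0.73, with 0.32 when 0.1 was added. With LPS the eicosanoid list (median −0.33) was down with camera (adjusted p = 0.683) and up with fry (0.00547).

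Depth is unknown, so a value at 0 does not show that a transcript was absent.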

Other observations

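The leukocyte tests of this part and the splits were chosen after the results were seen.

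Receptors and transporters of other prostaglandins moved with PGD2 alone: Ptgir rose by 2.23 ± 0.15 (SE, limma adjusted p = 3.13e-06), Ptger2 by 2.64 ± 0.19 (adjusted p = 3.43e-06) and Abcc4 by 1.61 ± 0.24 (adjusted p = 0.00057), and Ptger4 fell by 1.27 ± 0.19 (adjusted p = 0.000533). As a list, with 4 of 5 higher and 1 lower (4 and 1 adjusted over the list alone), they had a median of 1.61 (camera adjusted p = 0.0342, adjusted p = 0.233 with an estimated correlation), which was not past the threshold without LPS and vehicle library 1 (0.052). Among genes of lipid handling, Plin2 rose by 1.91 ± 0.13 (adjusted p = 3.43e-06) and Cd36 by 1.47 ± 0.13 (adjusted p = 1.75e-05), although Pparg fell by 1.42 ± 0.22 (adjusted p = 0.000581), and the list as a whole, with 7 of 15 higher and 2 lower (7 and 3 adjusted over the list alone), was not past the threshold (camera adjusted p = 0.186, adjusted p = 0.643 with an estimated correlation). The prostaglandin E synthase gene Ptges rose by 1.65 ± 0.16 (adjusted p = 2.55e-05). S100a8 rose by 3.46 ± 0.48 with PGD2 alone (adjusted p = 0.000304), by 3.07 ± 0.48 with LPS and by 2.05 ± 0.48 with PGD2 after LPS (adjusted p = 0.011).

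In the tuft tables, the endothelial-type gene Tek was listed at 0 in all 3 non-tuft libraries of both tissues and was at 5.49 ± 1.24 (SD, limma adjusted p = 0.00932) in pancreatic and 5.16 ± 0.71 (adjusted p = 0.000942) in intestinal tuft libraries. It kept its call in 0 of 6 fits without a library in the pancreas (0.0521 to 0.158) and in 6 of 6 in the intestine. Esam rose by 3.83 ± 0.58 (SE, adjusted p = 0.00348) and Plvap by 2.94 ± 0.79 (adjusted p = 0.0396) in the intestine, the latter kept in 1 of 6 fits without a library. As a list, endothelial genes rose in the intestine at 3 of 4 members (3 and 0 adjusted over the list alone). Their median was 3.39 (camera adjusted p = 0.00455, adjusted p = 0.117 with an estimated correlation). In the pancreas 1 of 5 rose (1 and 0 adjusted over the list alone), and the list was not past the threshold (median 0.54, camera adjusted p = 0.132). Gastric-type genes were higher as a list in the pancreas with camera (median 1.59, adjusted p = 0.0116, adjusted p = 0.442 with an estimated correlation), with 1 of 14 higher and 1 lower (4 and 1 adjusted over the list alone), and the call was kept in 3 of 6 fits without a library (highest 0.221). Of its members, Tff1 rose by 4.12 ± 0.86 (adjusted p = 0.0486), with tuft libraries at 14.38, 10.13 and 11.88, and Muc6 fell by 1.97 ± 0.38 (adjusted p = 0.0361). Tff1 and Muc6 kept their calls in 0 of 6 fits without a library. Early-response genes of tissue dissociation were lower as a list with camera in tuft libraries of both tissues. In the pancreas 0 of 16 were past the threshold (0 and 0 adjusted over the list alone), with a median of −0.79 (camera adjusted p = 0.000482, adjusted p = 0.404 with an estimated correlation). In the intestine 4 of 14 were lower (0 and 4 adjusted over the list alone), with a median of −1.09 (camera adjusted p = 0.00662, adjusted p = 0.232 with an estimated correlation). Among the 4, Egr1 fell by 3.71 ± 0.61 (adjusted p = 0.00495).

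Genes known from leukocytes, such as Rac2, Hck and, in the intestine, Ptprc, were higher in the tuft libraries although the cells were stained for Cd45; how that stain was gated was not read. Leukocytes in the sort as the whole source of Rac2 are argued against by the other abundant transcripts below, which they would bring too, but not by Ptprc in the intestine. In the pancreas Rac2 was at 8.54 against a median of 2.25 for 8 other abundant leukocyte transcripts (highest Cd52, 3.38, from 0, 5.46 and 4.68 in libraries 1, 2 and 3), a gap of 6.29. In the intestine it was at 11.08 against 1.66 for 6 others (highest Ctss, 2.18), a gap of 9.43; the limit set for either was 3. Of these 6, 4 are myeloid (Lyz2, Cd68, Ctss and Cd14), which lymphocytes would not bring, and only Cd37 (1.58) and Coro1a (1.7) are pan-leukocyte. Ptprc was not among the other transcripts. In the intestinal tuft libraries its mean, given earlier, lay within the limit of 3 from Rac2, as leukocytes would give. In the pancreas it was higher than Cd52 in each tuft library. The myeloid list was not past the threshold in the pancreas (0 of 11 members past it, median 0.07, camera adjusted p = 0.683). Nor was it in the intestine (median −0.68, camera adjusted p = 0.49), where 0 of 4 members rose and 1, Ctss, fell. The intestinal lymphocyte list had 0 of 3 members past the threshold (median 0.72, camera adjusted p = 0.49). Ptprc and the levels of the other transcripts leave a share of leukocytes open, as do the mast cell and lymphocyte lists in the pancreas, with medians of 2.28 and 2.09. Expression of Rac2 by the tuft cells themselves may explain the rest, as a hypothesis found on these libraries.

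With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of these comparisons 1 split, the real one, gave as many genes. It gave 244 in the pancreas and 1752 in the intestine (highest other 0 in both), 5691 with LPS (0), 2912 with PGD2 alone (1) and 2166 with PGD2 after LPS (2).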
